A study of Escherichia coli and Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

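Total RNA of HG228 and of MG1655 in exponential phase was compared on 2 arrays of 2 colours. Per the labels' protocols, the RNA was purified with a commercial kit, polyadenylated and labelled with an Agilent amplification kit. Per the labels, HG228 carried Cy3 and MG1655 carried Cy5 on both arrays. The dyes were not swapped, so a dye effect cannot be told apart from the strain difference. The array design, scanner, image software, background correction, normalization and filters are not given in the sources used here.

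The authors deposited 1 log ratio per feature, named as an average in the file's header, and it was read as the mean over the 2 arrays of the log of an intensity ratio. That reading rests on the names of the column and table alone. All values lie within a narrow range of 0, and whether the column holds another quantity was not settled. The deposited values carry no log base, and their direction is not settled. The name of the table puts HG228 before MG1655, whereas a ratio of Cy5 over Cy3, as Agilent software writes it, would put MG1655 over HG228. Signs were kept as deposited and no strain was assigned to them. Values were converted to folds under base 10, the natural base and base 2. A fold threshold of 2 was applied on the base-10 reading, which gives the widest folds, and then on the others. The table held 4093 IDs, each once, with 0 blank values and 0 values of exactly 0. No per-array value or signal intensity was used here, so the spread between arrays, the detection of each feature and the depth of the signal are unknown.

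Before the data were examined, a limma test was planned for the case that values per array were present, and a description without a test for the case that only means were. The second case applied. Also before the data were examined, 37 gene lists with 751 entries, 18 single genes and a rule for naming the 12 highest, the 12 lowest and set members of each list were fixed by gene symbol. The table names features by ID only, and no table pairing the IDs with symbols was used here. The lists were therefore not tested, and the rule named no gene. In their place, the 2 highest and 2 lowest IDs are given.

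What was computed from the deposited values, with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, is their distribution and their order along the ID numbers. Figures were drawn with matplotlib 3.10.9. The robust SD was 1.4826 times the median absolute deviation from the median, and a tail began 2 robust SDs from the median. Similarity of neighbours was Pearson's r between each value and the next in order of ID number, set against 10000 shuffles of the values (seed 20). These shuffles describe the order of values in the table and do not test the strains. The limit of 2 robust SDs was fixed before the data were examined, as an alternative to the fold threshold. The separate counts of each tail, their distance from 0 and the comparison of neighbours were chosen after the table was seen. Each alternative for the neighbour pairs was set against 10000 shuffles put through the same alternative. The scripts were tested on simulated data with the same 4093 IDs. All of 200 IDs shifted by 5 robust SDs, 100%, fell beyond the tail limits, against 3.96% of the unshifted ones. The shift lay far beyond the limit of 2 robust SDs, so this checked the code and not the power to find smaller differences. A neighbour correlation set at 0.3 was found as 0.288. Alternatives covered the fold threshold, the log base, the centring, the sign, the tail limit and the choice of neighbour pairs.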

Results

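The gene expression of HG228, an ethanol-tolerant strain of Escherichia coli, was compared with that of MG1655, the K-12 strain from which HG228 was derived. Both strains were grown to mid-log phase in minimal medium that held ethanol at 1.5% by volume and glucose at 0.04% by weight, so the comparison addressed how their transcripts differed during growth in ethanol. RNA of both strains was hybridized to the same 2-colour arrays, with HG228 labelled with Cy3 and MG1655 with Cy5. There were 2 arrays, described as biological replicates. The deposited table gave 1 mean log ratio for each of 4093 feature IDs and no value per array, so no SD, interval or p-value of the strain difference could be given, and the values below are the authors' averages. The number of arrays limits their precision. Neither the log base nor the strain in the numerator was stated. The column was read as the log of an intensity ratio from its name, and how the 2 arrays were averaged was not stated, so the folds below hold only under that reading. "Higher" and "lower" therefore refer to the deposited value and not to a strain.

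Read as the log of a ratio, no deposited mean reached 2-fold under base 10, the natural base or base 2. The values ranged from -0.245 to 0.206, with a median of 0.0243 and a robust SD across IDs of 0.0299. Read as base-10 logs, the lowest value was a 1.76-fold difference and the highest a 1.61-fold difference. Read as natural logs, the same values were 1.28-fold and 1.23-fold, and read as base-2 logs they were 1.19-fold and 1.15-fold. At a 1.5-fold threshold, 2 IDs were higher and 5 were lower on the base-10 reading, and none on the other readings. Subtracting the median of all IDs left 0 IDs at 2-fold on all 3 readings, and gave 2 higher and 7 lower IDs at 1.5-fold on the base-10 reading.

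The feature IDs have the form of locus tags of E. coli K-12, the letter b followed by a number. The table paired none of them with a gene name, and no annotation was used here, so the pathways behind these values could not be described. The highest value belonged to b1307, at 0.206, which was 6.07 robust SDs above the median. The ID numbered directly after b1307 had a value of 0.104, higher than 99.1% of all IDs, and the one directly before it had 0.0606, higher than 89.3%. The second highest value, 0.203, belonged to b3119, which was 5.97 robust SDs above the median. Its neighbours in number did not share its position. They had values of -0.0458 and -0.0256, higher than only 3.54% and 7.99% of all IDs. The lowest value, -0.245, belonged to b3556, at 9.02 robust SDs below the median, and the IDs numbered directly before and after it had -0.00888 and -0.0451. The second lowest, -0.241, belonged to b3238, at 8.88 robust SDs below the median. The ID numbered directly before b3238 had -0.168, higher than only 0.122% of all IDs, whereas the one directly after it had 0.0347, higher than 63.6%. None of these values has an error estimate, and robust SDs here measure the spread across IDs, not between arrays.

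The distribution was shifted above 0 and had a longer lower than upper tail. Of the 4093 IDs, 3183 (77.8%) had a value above 0 and 910 (22.2%) a value below 0. Lower values reached further from the median than higher ones. The lower tail, more than 2 robust SDs below the median, held 226 IDs (5.52%), and the upper tail held 107 IDs (2.61%), where a normal curve of the same median and robust SD would put 93.1 IDs in each. At 3 robust SDs the counts were 80 lower and 18 higher, against 5.53 in each tail of the normal curve, and at 5 robust SDs they were 13 lower and 2 higher. This split depended on the centring. Measured from the median, 67.9% of the 333 IDs beyond 2 robust SDs were lower, but measured from 0, 93 were lower and 462 higher, so that 16.8% were lower.

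**Figure D1:**
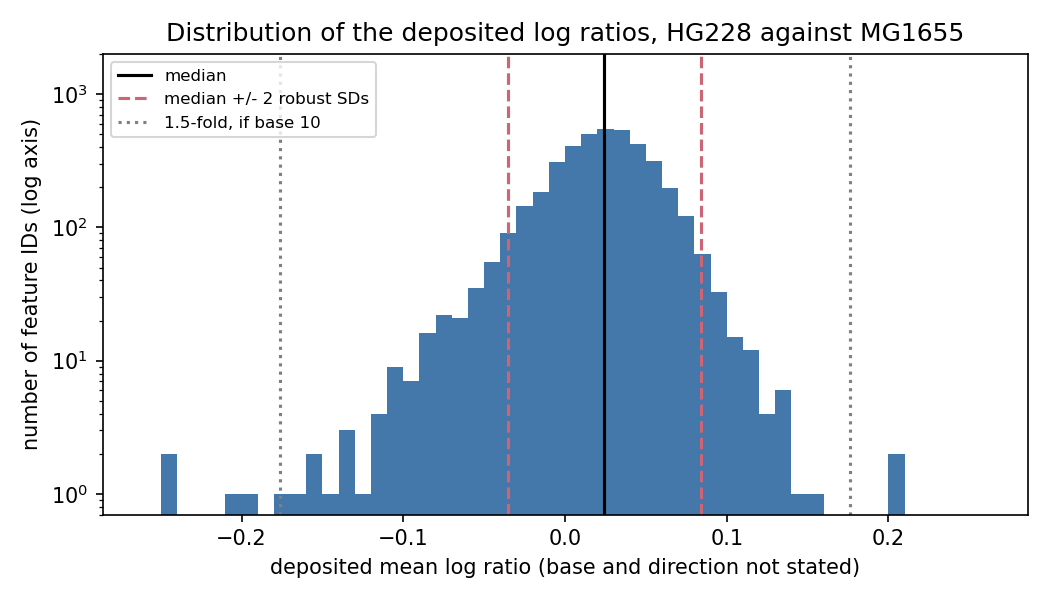
Number of feature IDs (log axis) by deposited mean log ratio, in bins of equal width, with the median (solid line), the limits 2 robust SDs from it (dashed lines) and the 1.5-fold limits that would apply if the logs were base 10 (dotted lines). The values run from -0.245 to 0.206, with 226 IDs below the lower dashed line and 107 above the upper one.

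IDs that followed each other in number had similar values. In E. coli K-12 these numbers were first given in order along the chromosome, where neighbouring genes are often transcribed together. Pearson's r between each ID and the next in the list was 0.280 and Spearman's rho 0.279. In 10000 shuffles of the values over the IDs, r stayed between -0.0677 and 0.0570. These correlations are across IDs of 1 table, and IDs are not independent replicates. At larger distances in the list r was lower, at 0.164 for 2 positions apart, 0.115 for 3, 0.0873 for 4 and 0.0498 for 5, and beyond that it did not fall steadily, at 0.0295 for 6, 0.0525 for 8, 0.0203 for 10, 0.00202 for 20 and 0.00929 for 50.

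IDs of the same tail lay next to each other more often than in the shuffles, although most IDs in the tails had no such neighbour. Of the pairs of neighbours, 68 had both members in the same tail, 52 of them lower and 16 higher, where the shuffles gave a median of 15 and at most 33. A further 7 pairs joined opposite tails, a number within the range of the shuffles (1 to 27, median 12). Of the 226 IDs in the lower tail, 94 had a listed neighbour in the same tail, and of the 107 in the upper tail, 30 had one. There were 6 lower runs of 3 or more IDs, the longest of 7, and 1 upper run, of 4.

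**Figure D2:**
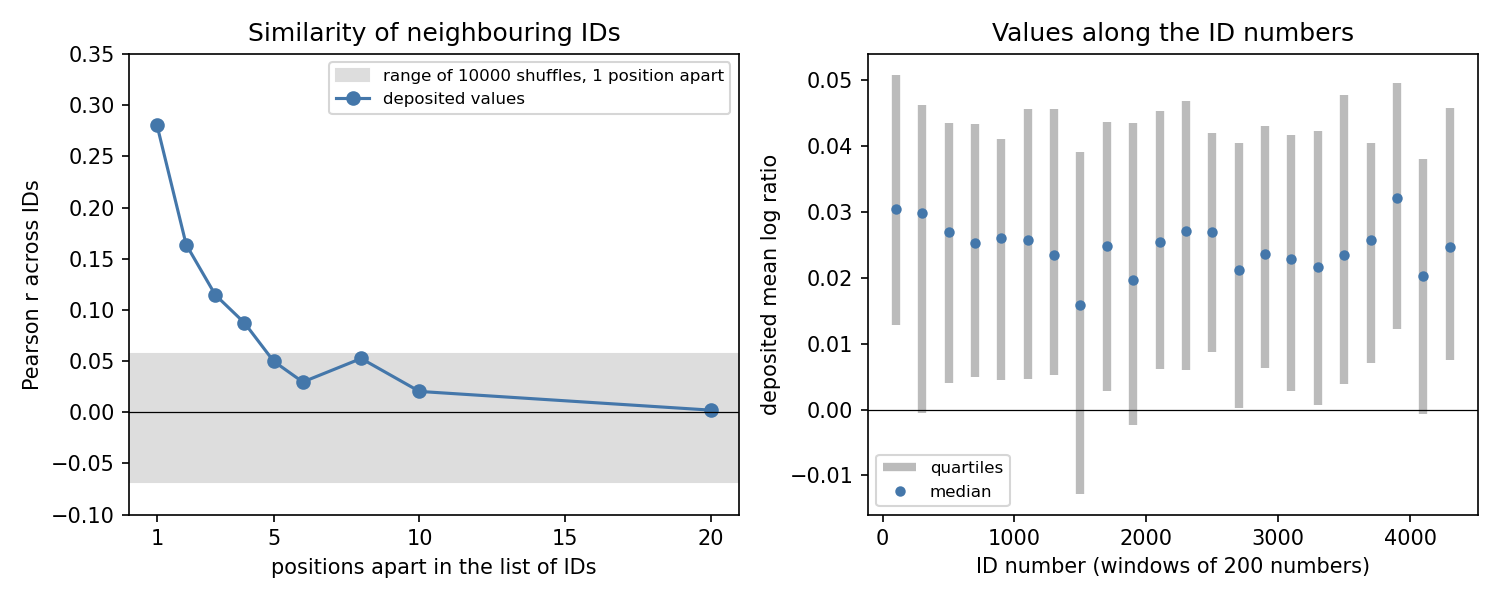
Left, Pearson's r across IDs (vertical axis) between deposited values a given number of list positions apart (horizontal axis), with the range of 10000 shuffles for neighbours in grey. Right, the median (points) and quartiles (bars) of the deposited mean log ratio in windows of 200 ID numbers below 4400. The correlation is 0.280 between neighbours, 0.0498 at 5 positions, 0.0525 at 8 and 0.00202 at 20, and the window medians lie between 0.0158 and 0.0322.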

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

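The alternatives to the count of IDs at 2-fold, the limit of 2 robust SDs among them, were chosen before the data were examined. All other measures and their alternatives, the distance from 0 included, were chosen after. The count of IDs at 2-fold or more on the base-10 reading was 0, and 0 with the median subtracted. A 3-fold limit, base-2 or natural logs and the turned sign cannot raise it, so their counts of 0 say nothing of stability. It was 7 at 1.5-fold and 333 beyond 2 robust SDs from the median. With the sign turned, by construction, the higher tail held 226 IDs and the lower 107, and 22.2% of IDs were above 0. The 107 higher and 226 lower IDs became 18 and 80 at 3 robust SDs, and 462 and 93 when distance was taken from 0. With the median subtracted, which fixes the balance, 49.99% of IDs were above 0. Without the late-numbered IDs (numbers from 4400), and with the median and robust SD taken anew from the rest, the tails held 106 and 214 IDs. These counts were within 1.5 times of the 107 and 226. Over the 264 pairs with a gap in number the correlation of neighbours was 0.187. The highest r at those pairs in 10000 shuffles of all values was 0.247, and 18 shuffles reached 0.187. In the other 6 alternatives the correlation of neighbours was 0.211 to 0.284, above the highest shuffle put through the same alternative. The median of late-numbered minus other IDs was -0.0210, and by construction 0.0210 with the sign turned. The difference was -0.0143 with the tails left out and -0.0274 with means in place of medians. No replicate could be left out, no gene list median was computed, and averaging of several rows per gene and removal of values at 0 had nothing to act on, since the table holds 1 mean per ID and none at 0. Signal over background is unknown, so no limit of detection can be given.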

Other observations

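All tests in this part were chosen after the values were seen.

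Neighbouring IDs had similar values, with r = 0.280. Independent error of each ID is argued against by the shuffles, whose highest r was 0.0570. A slow drift along the table is argued against as the whole source, since r was 0.237 after a running median over 51 IDs was subtracted, against at most 0.0496 in shuffles treated alike. A few extreme runs are argued against in the same way, since r was 0.211 over the 3501 pairs with neither ID in a tail, against at most 0.0667 in shuffles treated alike. Shared transcripts of neighbouring genes are a candidate explanation that stays open. Over the 264 pairs with a missing number between them, r was 0.187. The range that held 95% of random sets of as many pairs was 0.141 to 0.418. This comparison cannot decide the question, because IDs with a missing number between them may still share a transcript and consecutive ones need not. Late-numbered IDs (numbers from 4400) were not left out of these pairs. Similarity of base composition or of place on the array was not tested.

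The 105 late-numbered IDs, with numbers from 4400 up, had lower values than the other 3988. In the K-12 numbering such IDs were mostly added after the first annotation. Their median was 0.00381 against 0.0248, and 24.8% of them lay in the lower tail against 5.02% of the others. Whether an ordinary stretch of neighbouring IDs could look like this stays open, because the values went both ways: among 3884 overlapping stretches of 105 other IDs, 14, all between the numbers 1451 and 1586, had a median as low, the lowest being 0.00150, but 0 had as many IDs in the lower tail, the most being 21 against 26. Random sets of IDs had no median as low as 0.00381, the lowest being 0.0105, so a random draw of IDs is argued against. Such sets ignore the similarity of neighbours. Whether late-numbered IDs lie next to each other on the chromosome was not tested, so which comparison suits them is not settled. The difference between late-numbered and other IDs depended on where the limit was placed. It was -0.00711 for the 196 IDs from 4300 and -0.0311 for the 67 from 4500. The late-numbered IDs also had a wider spread, with a robust SD of 0.0433 against 0.0296. Their share in the lower tail may therefore reflect spread as well as a lower median. The upper tail held no excess of them, with 1.90% of the late-numbered IDs against 2.63% of the others. Weak signal and feature length were not tested.

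A hypothesis was that values would follow 1 slow wave along the numbers, as a difference in gene dosage around the chromosome might give. The fitted wave was 0.00290 from peak to trough, or 0.0969 robust SDs, with its peak at number 4110 and its trough at 1910. Of 10000 shuffles of blocks of 20 neighbouring IDs, 47.3% gave one as large, so chance order of blocks could not be excluded. The shuffles compared the size of the wave only, and the place of its peak was not tested. The highest window median, 0.0322, was at numbers 3800 to 3999 and the lowest, 0.0158, at 1400 to 1599. In 1 set of simulated values with neighbours alike, a wave of 0.01 was found as 0.00872. That wave was larger than the fitted one, and the highest block shuffle reached 0.00973. The simulation therefore checked the fit, and did not show that a wave of the fitted size would stand out.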
